A study of Mus musculus with 16 samples.

How the data were processed

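Per the labels' protocols, primary astrocytes from wild-type mouse brain were grown in DMEM with GlutaMAX, fetal bovine serum and antibiotics, and received 10 µg/mL APOA1 for 24 h or a matching volume of phosphate-buffered saline. RNA was extracted with RNeasy columns and DNase, and libraries were made from polyadenylated RNA with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, the software was FastQC 0.12.1, MultiQC 1.27, STAR 2.7.11b, featureCounts 2.0.8 and DESeq2 1.44.0 with the GRCm39 genome. The role of each tool is not spelled out in those notes.

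The unit of the deposited table is a signal, counts per gene that the authors normalized for library size with DESeq2, in 16 columns for 8 untreated and 8 APOA1 libraries. Of 238560 values, 100% were whole reads divided by 1 factor per library, within 1e-06 reads, so whole reads were recovered and used only for alternative tests and for depth. A single read was worth 0.875 to 1.12 in these units. Every gene of the table had 10 reads or more in at least 8 libraries, so genes with few reads were absent and a gene missing from it says nothing about its level.

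The comparison, the test, the filter, the alternatives, the rule for naming genes and the 35 gene lists were fixed before the data were examined. Genes with a mean value under 10 over all libraries were left out (46 of 14910), and 14864 were kept. Values were used as log2(value + 1), a pseudocount that affects the fold change of genes with few reads. Log2 changes are differences between group means of log values. For genes with few reads they can be larger or smaller than the ratio of group means. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, without covariates or blocks, 14 residual degrees of freedom, and Benjamini-Hochberg adjustment over all kept genes at 0.05, 2-sided. Folds given in the text are ratios of group means of the normalized values.

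Named genes were Abca1, the 12 largest rises and the 12 largest falls among genes passing the test with a mean of at least 50 in the higher group, and the 4 members of smallest p in each of 22 described lists; not every gene so picked is reported here. Called genes without a proper symbol were skipped by that rule and counted (42). Genes outside it are said in the text to have been chosen after their values were seen. Where a list was counted, each member was judged with p adjusted over all genes and again adjusted over the list alone.

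Lists were tested with camera from limma, preset correlation 0.01 between genes and ranks off, and Benjamini-Hochberg adjustment over the lists, then with an estimated correlation, and with fry. They covered cholesterol synthesis, LXR targets and lipid efflux, fatty acid synthesis and desaturation, fatty acid oxidation, APOA1 binding and receptors, NF-kB cytokines and chemokines, interferon-stimulated genes, antigen presentation, complement, pan-reactive, A1 and A2 astrocyte states and astrocyte homeostatic markers. They also covered Alzheimer's disease risk, lysosome, NRF2, unfolded protein response, heat shock and metallothionein, proliferation, extracellular matrix, TGF-beta and YAP response, neurotrophic and growth factors, synapse regulation, immediate early genes, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrially encoded genes. The last lists held markers of microglia, oligodendrocyte lineage, neurons, endothelium, pericytes and smooth muscle, fibroblasts and meninges, and ependyma and choroid plexus.

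Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, equal upper quartile or equal total scaling, limma without the trend, with robust moderation or with weights per library, replicate number as a block, each library left out in turn, edgeR 4.0.16 quasi-likelihood with TMM and DESeq2 1.42.0 on the recovered reads, an adjusted p under 0.1, a minimum log2 change of 0.5, and the estimated correlation. After the principal components were seen, 4 were added: leaving out replicates 7 and 8, using them alone, a covariate for that set of replicates, and a minimum log2 change of 1. GC content and length came from transcripts of another mouse annotation, for 14313 of the 14864 genes (96.3%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

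The main procedure was tested on simulated data with the same 14864 genes and 8 libraries per group. It recovered 64% of 50 genes changed by 0.25 on the log2 scale, 96% of those changed by 0.5, 98% at 1 and 100% at 2. Of 14664 unchanged genes 8 were called, 4.28% of all calls. The simulation changed few genes, equally up and down, and held no difference between sets of replicates. It therefore cannot show the share of false calls in the real comparison, where 75.9% of genes were called. In the simulated data camera called the raised set and 0 of 50 random sets. These random sets cannot show whether the preset correlation limits false calls among the real lists, because genes of a real list can vary together. The correlation estimated within the real lists ran from -0.0346 (endothelial markers) to 0.775 (immediate early genes). Median residual SD in the real data was 0.0798 on the log2 scale. Libraries of a group correlated at 0.991 to 0.993 and libraries of different groups at 0.937 to 0.947 (Pearson's r). Raw sequence files were not used here, and no library was left out of the main test.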

Results

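The series concerns blood-borne proteins that reach the brain, and this part of it asked how mouse astrocytes respond to APOA1, the main protein of high-density lipoprotein particles. Primary wild-type mouse brain astrocytes were cultured in serum-containing medium and given 10 µg/mL APOA1 for 24 h, or the same volume of saline. RNA-seq of polyadenylated RNA was made from 8 untreated and 8 APOA1 samples, numbered as replicates 1 to 8 of each group, and the deposited table gave normalized read counts for 14910 genes. The reads recovered from these values came to 82.8 to 97.5 M (M, 1e6 reads) per untreated library, with a mean of 91.5 ± 5.07 M (SD, n = 8). The APOA1 libraries held 91.0 to 114 M, with a mean of 101 ± 8.04 M (SD, n = 8). Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical in part.

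APOA1 was followed by a very broad change in which inflammatory genes rose by the largest amounts. Lcn2, which encodes the siderophore-binding protein lipocalin-2, went from 1572 ± 256 to 695820 ± 39248 normalized reads (mean ± SD, n = 8 each), a 443-fold rise. Saa3, an acute-phase serum amyloid A, rose 2189.7-fold from 166 ± 61.7 to 363422 ± 45299.6, and Marco, a scavenger receptor of macrophages, rose 3743-fold from 13.3 ± 10.1 to 49819 ± 5661. The deepest fall was that of Gpr34, a lysophospholipid receptor typical of microglia, from 944 ± 125 to 8.72 ± 5.69, which is 108-fold lower. Of 14864 genes kept, 11286 (75.9%) differed in limma's moderated test on log2 values after Benjamini-Hochberg adjustment, 5684 higher and 5602 lower with APOA1. Most differences were small, with a median size of 0.33 on the log2 scale among the called genes and 7159 of them under 0.5. By at least 1 on that scale, 998 genes were higher and 1007 lower, and by at least 3 the numbers were 248 and 36.

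The 12 largest rises picked by the naming rule included chemokines, cytokines, acute-phase proteins and enzymes of activated macrophages. On the log2(value + 1) scale Marco rose by 11.97 (SE 0.225, limma adjusted p = 7.32e-22), Saa3 by 11.16 (SE 0.154, limma adjusted p = 3.84e-24) and the neutrophil chemokine gene Cxcl3 by 10.55 (SE 0.445, limma adjusted p = 1.65e-15). Nos2, the inducible nitric oxide synthase, rose by 9.70, Csf3, the granulocyte colony-stimulating factor, by 9.48, and Arg1, arginase 1, by 9.03. Lcn2 rose by 8.80, the chemokine gene Ccl5 by 8.51, interleukin-1 alpha (Il1a) by 8.35, the protease inhibitor gene Csta2 by 8.02 and Acod1, which makes itaconate, by 8.01. Saa2 had 0 reads in all 8 untreated libraries and 334 ± 36.7 normalized reads with APOA1, at least 109-fold higher against a floor of 3 reads per library. Cxcl3, Nos2, Csf3 and Csta2 were near that floor in the untreated libraries, with means of 3.86, 3.44, 2.34 and 2.86 normalized reads, so their fold changes are imprecise. Saa2, Saa3 and Csta2 belong to families of closely similar genes, whose shared reads could have been assigned to a neighbour or dropped.

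The 12 largest falls included genes typical of microglia and of multiciliated cells. Gpr34 fell by 6.95 (SE 0.396, limma adjusted p = 3.92e-13), Cmah, which makes N-glycolylneuraminic acid, by 6.78 (SE 0.545, limma adjusted p = 1.79e-10) and the organic anion transporter gene Slco2b1 by 6.00 (SE 0.118, limma adjusted p = 1.52e-21). Ltc4s, leukotriene C4 synthase, fell by 5.27 and the protease gene Ctse, cathepsin E, fell by 4.66. Mcidas, a regulator of multiciliated cells, fell by 4.66 from only 52.3 ± 30.6 normalized reads. The rest were Myh8 at -4.24, Prss56 at -4.20, Cdc20b at -4.08, Asb10 at -4.01, the olfactory receptor gene Or10ad1 at -3.85 and Caln1 at -3.79. Mcidas, Cdc20b, Asb10, Cmah and Caln1 had the lowest means with APOA1, at 1.24, 3.59, 4.56, 6.44 and 7.13 normalized reads, so their fold changes are imprecise. For each of the 110 genes picked by the naming rule, all 8 APOA1 libraries lay on the same side of all 8 untreated libraries. Apart from Abca1 these genes were picked for large changes or small p, which nearly fixes that outcome. Among all 14864 genes kept, the groups were separated in this way for 3665 higher and 3585 lower genes, against 0.0155% of genes by chance. When each library was rescaled to equal upper quartiles the calls split into 4158 higher and 7141 lower, and with equal totals into 4278 and 7004. These rescalings shift the median of all genes by -0.09 and -0.08 on the log2 scale.

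**Figure D1:**
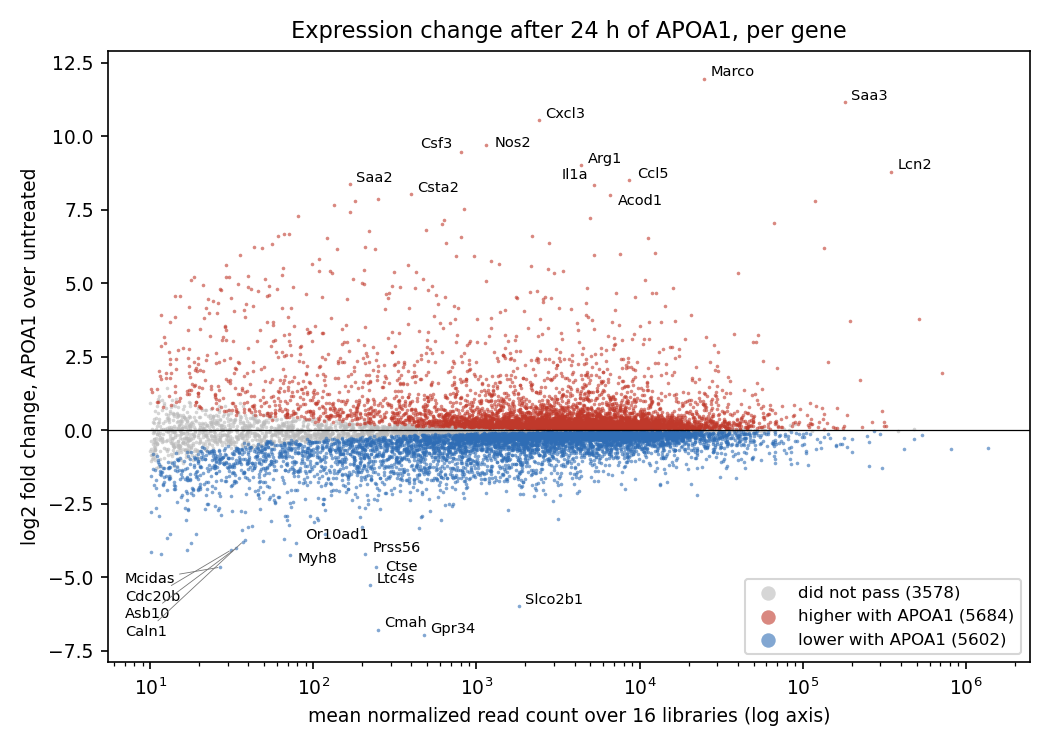
Log2 fold change of each gene (APOA1 over untreated, 8 libraries each) against its mean normalized read count on a log axis, with points coloured by the limma test and the 24 genes of largest change named. Rises reach 11.97 (Marco) and falls -6.95 (Gpr34), while most of the 11286 called genes lie close to 0.

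Every measured member of the list of NF-kB-driven cytokines and chemokines rose. All 29 of 29 were higher, by a median of 3.68 and a range of 1.06 to 11.16 on the log2 scale (camera adjusted p = 1.33e-15), with adjusted p = 0.0855 with an estimated correlation between the genes. The median was 3.92 without replicates 7 and 8, which stood apart from the others, and 3.35 with them alone. Vcam1, a leukocyte adhesion molecule, rose 9.66-fold from 7147 ± 319 to 69029.5 ± 3669 normalized reads (SD, n = 8), the chemokine gene Cxcl5 rose 64.9-fold from 375 ± 53.4 to 24378 ± 1577, and Sod2, mitochondrial superoxide dismutase, rose 4.55-fold from 10758 ± 387 to 48962 ± 2424. Among interferon-stimulated genes 28 of 29 rose, with a list median of 3.04 (camera adjusted p = 3.22e-17), and adjusted p = 0.0652 with an estimated correlation. Isg15, a ubiquitin-like antiviral protein, rose 28.8-fold from 321 ± 38.5 to 9249.8 ± 588, Usp18, which removes it from proteins, rose 23.1-fold, the RNA sensor gene Rigi 5.54-fold and the guanylate-binding protein gene Gbp3 8.56-fold. Ifit2, singled out after its values were seen, was the exception at -0.07, a small fall that did not pass without replicates 7 and 8. All 18 of 18 genes of antigen presentation rose, by a median of 2.45 (camera adjusted p = 2.28e-12), and adjusted p = 0.0652 with an estimated correlation. The class I light chain gene B2m rose 5.09-fold from 18638 ± 747 to 94910 ± 3895, the peptide-loading gene Tapbp 3.47-fold, and the class I genes H2-D1 and H2-K1 7.97-fold and 7.93-fold. H2-D1, H2-K1 and the Gbp genes have near-identical relatives, so the division of reads among them is uncertain. Of 24 microglia markers, 10 rose and 12 fell alongside these lists, with a median of -0.15 (camera adjusted p = 0.441).

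Counts of called members did not depend on whether p was adjusted over all genes or adjusted over the list alone in 30 of the 35 lists, and the other counts are given with their lists. Limma's camera test called 16 of the 35 lists, 11 upward and 5 downward, with its preset correlation of 0.01. With an estimated correlation camera called 0 of them after adjustment, and 9 reached an unadjusted p under 0.05. The fry test, which asks only whether members move on balance one way, called 31 lists, and its mixed form called 35.

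**Figure D2:**
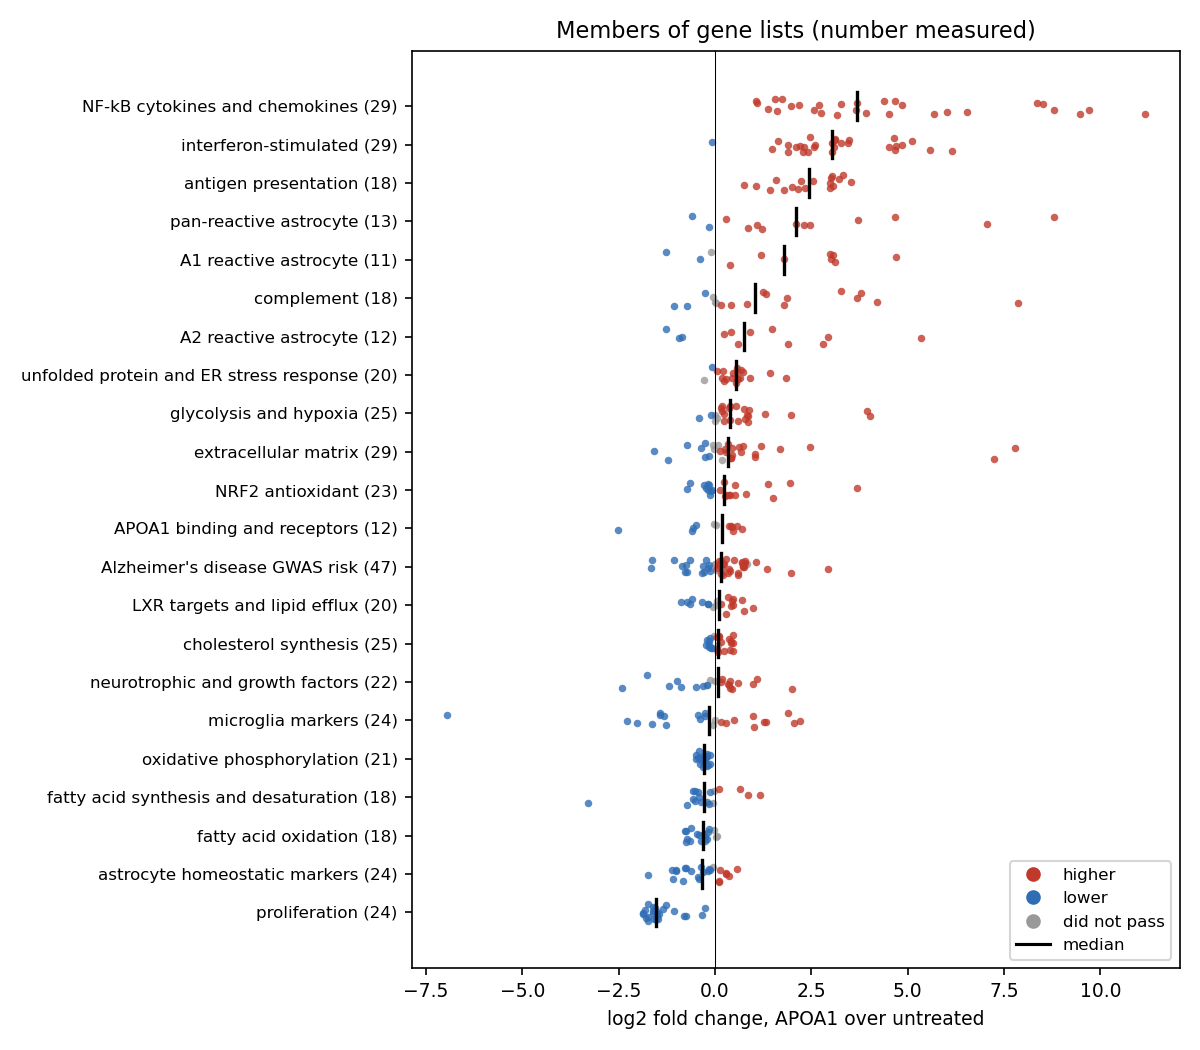
Log2 fold change (APOA1 over untreated, 8 libraries each) of every measured member of 22 gene lists, 1 point per gene coloured by the limma test, with the list median as a black bar. All 29 NF-kB members and all 18 antigen presentation members lie above 0, and all 24 proliferation members lie below it.

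Complement genes rose for the most part. C3, the central component, went from 70542 ± 11978 to 960936 ± 47829.6 normalized reads (SD, n = 8), 13.6-fold higher, and the properdin gene Cfp rose 18.6-fold. C1ra and C1s1, the proteases of the first complement complex, rose 12.9-fold and 9.64-fold. Of 18 measured genes 12 rose and 3 fell, with a median of 1.03 (camera adjusted p = 0.00421), and adjusted p = 0.463 with an estimated correlation. C1qa, C1qb and C4b, named after their values were seen, did not pass, at 0.01, -0.05 and 0.02.

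Markers of reactive astrocytes rose whether they belonged to the shared set, to the set linked to inflammation (A1) or to the set linked to ischaemia (A2). Of 13 pan-reactive genes 11 rose, with a median of 2.10 (camera adjusted p = 7.87e-06), and adjusted p = 0.108 with an estimated correlation. Steap4, a metalloreductase, rose 132-fold from 1005 ± 195 to 132849 ± 7237 normalized reads (SD, n = 8), Cp, the ferroxidase ceruloplasmin, by 3.70 on the log2 scale from 27846 ± 597 to 362870 ± 9829, and Cd44, a hyaluronan receptor, 2.34-fold. The 2 pan-reactive genes that fell, named after their values were seen, were the intermediate filament genes Gfap (-0.60, from 1644570 ± 66072 to 1088180 ± 50862) and Vim (-0.17). Of 11 A1 genes 8 rose and 2 fell, with a mean of 1.68 on the log2 scale (camera adjusted p = 0.00221), and adjusted p = 0.0855 with an estimated correlation. H2-T23 rose 8.36-fold, the immunoproteasome gene Psmb8 8.03-fold and Gbp2 8.54-fold, and 6 of the A1 genes also stand in other lists. Fbln5 (2.43-fold lower) and Fkbp5 (-0.38) were the A1 genes that fell, again named after their values were seen. Of 12 A2 genes 9 rose and 3 fell, with a median of 0.75 (camera adjusted p = 0.0254), and adjusted p = 0.421 with an estimated correlation. The pentraxin gene Ptx3 rose 40.5-fold, the transglutaminase gene Tgm1 6.89-fold, Tm4sf1 2.78-fold and the transcription factor gene Stat3 1.86-fold. Cd109 (-1.26), Emp1 (-0.93) and S100a10 (-0.85) were the A2 genes that fell, named after their values were seen.

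**Figure D3:**
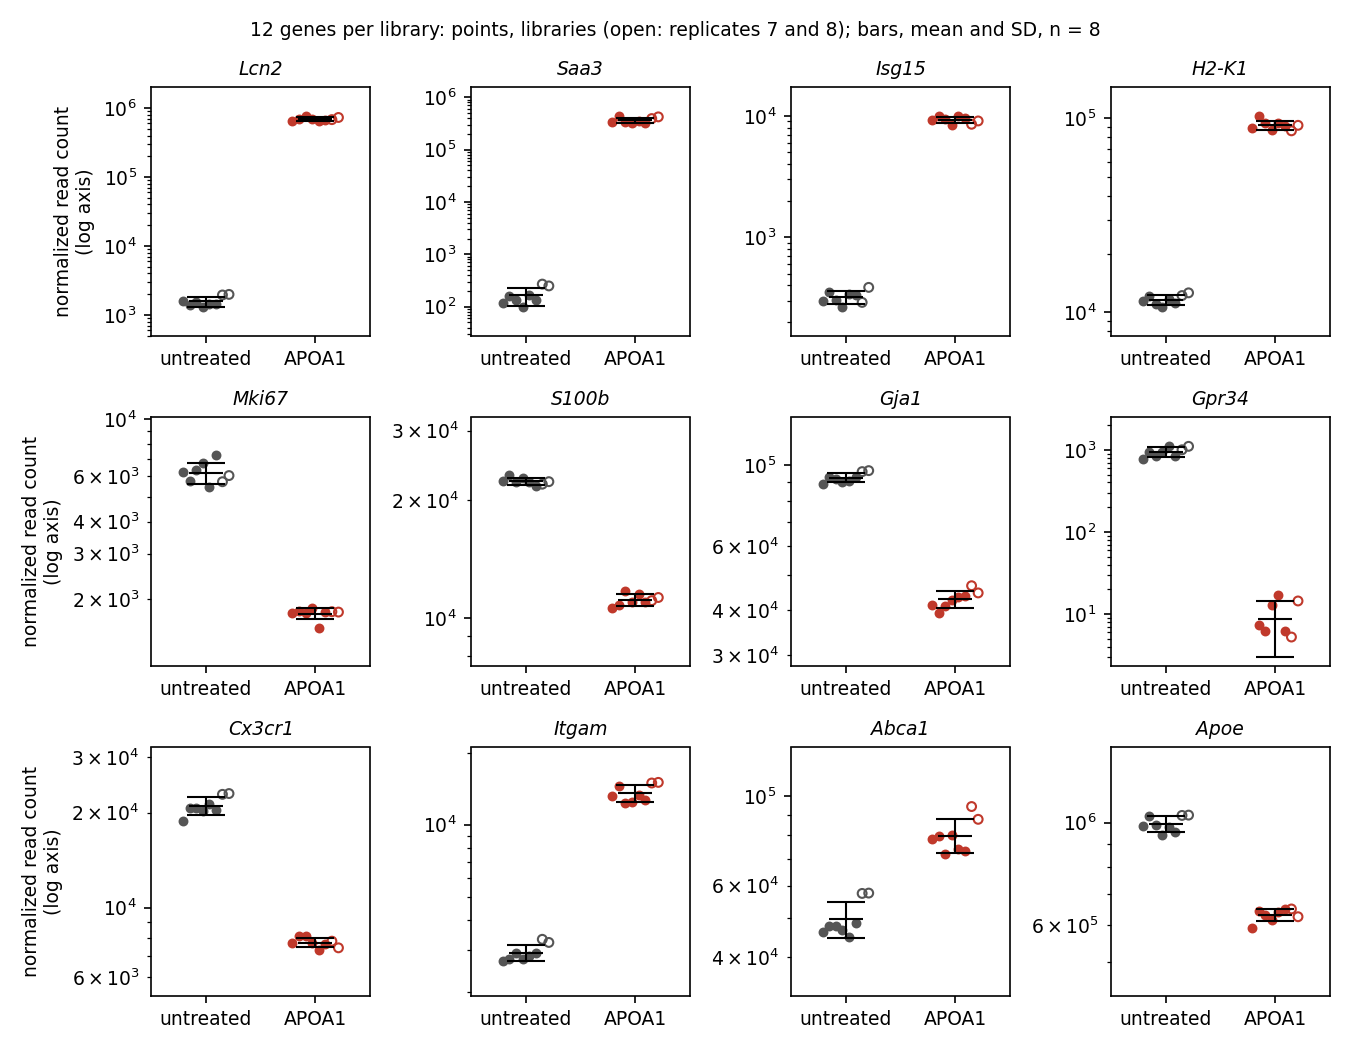
Normalized read counts (log axes) of 12 genes in each library, with points for libraries (open circles, replicates 7 and 8) and bars for the mean and SD of 8 libraries per group; a library at 0 for Gpr34 cannot be drawn on the log axis. In every panel the APOA1 libraries lie wholly above or wholly below the untreated ones.

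Markers of resting astrocytes mostly fell, by smaller amounts. S100b, a calcium-binding protein, went from 22337 ± 447 to 11141 ± 359.9 normalized reads (SD, n = 8), 2.00-fold lower, and Gja1, which encodes the gap junction protein connexin 43, from 92469 ± 2752 to 42818 ± 2271, 2.16-fold lower. Acsbg1, an acyl-CoA synthetase, was 2.03-fold lower, and Hepacam, a cell adhesion protein of astrocyte endfeet, 1.72-fold lower. Of 24 such markers 16 fell and 7 rose, with a median of -0.34 (camera adjusted p = 0.00421), and adjusted p = 0.421 with an estimated correlation. The water channel gene Aqp4 (0.29) and the glutamate transporter gene Slc1a2 (0.37), picked after their values were seen, were among those that rose.

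Genes of cell division fell together. Mki67, the Ki-67 proliferation antigen, went from 6199 ± 595 to 1754 ± 91.1 normalized reads (SD, n = 8), 3.53-fold lower, and the centromere gene Cenpf, the cyclin gene Ccna2 and the topoisomerase gene Top2a were 3.65-fold, 3.65-fold and 2.85-fold lower. All 24 of 24 proliferation genes fell, by a median of 1.53 on the log2 scale and from -1.87 to -0.27 (camera adjusted p = 5.67e-12), and adjusted p = 0.108 with an estimated correlation.

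APOA1 takes up cholesterol that cells release through the ABCA1 transporter, and the gene of that transporter rose moderately. Abca1 rose 1.61-fold, from 49525 ± 5031 to 79838 ± 7679.8 normalized reads (SD, n = 8), or 0.69 on the log2 scale (SE 0.0574, limma adjusted p = 3.27e-10). Apoe, the main apolipoprotein made by astrocytes, moved the other way, from 993530 ± 38842 to 631217 ± 19919, 1.57-fold lower. Nr1h3, which encodes the sterol-sensing receptor LXR alpha, rose 2.00-fold, Abca7 1.69-fold and Abca2 1.38-fold. Of 20 genes of the LXR and lipid efflux list 10 rose and 7 fell, and the list did not pass, with a median of 0.10 (camera adjusted p = 0.441). With equal upper quartiles its members split into 9 higher and 9 lower. Cholesterol synthesis genes did not pass as a list either, at a median of 0.07 (camera adjusted p = 0.291), with 14 of 25 higher and 8 lower; with equal upper quartiles the split is 9 to 9 and the median turns to -0.02, and with equal totals 9 to 9 and -0.01. The pathway enzyme genes Fdft1, Nsdhl and Fdps rose 1.31-fold, 1.34-fold and 1.39-fold. Among 12 genes of the list of APOA1 binding and receptors, not all of which encode proteins that bind APOA1, 6 rose and 4 fell. The median was 0.18 and the mean -0.11, without a call (camera adjusted p = 0.697, direction up). That median was 0.31 without replicates 7 and 8 and 0.11 with them alone. With equal upper quartiles it was 0.09, with 6 higher and 5 lower. P2ry13, a nucleotide receptor, fell 5.76-fold, the lipoprotein enzyme gene Lcat 1.53-fold and the ATP synthase subunit gene Atp5f1b 1.41-fold, while the RNA-binding protein gene Hdlbp rose by 0.35 on the log2 scale. Cubn (-0.56), named after its values were seen, was the remaining member that fell. Apoa1 itself was not analysed here.

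Fatty acid genes fell as groups, most of them by small amounts. For oxidation, Acadm, the medium-chain acyl-CoA dehydrogenase, went from 13686 ± 154 to 8246 ± 185 normalized reads (SD, n = 8), 1.66-fold lower, and Acaa2, Hadhb and Etfa, which act in the same mitochondrial pathway, fell by 0.76, 0.64 and 0.41 on the log2 scale. Of 18 oxidation genes 15 fell and 0 rose, with a median of -0.32 (camera adjusted p = 7.58e-05), and adjusted p = 0.0652 with an estimated correlation. Of 18 genes of fatty acid synthesis and desaturation 12 fell over all genes and 13 adjusted over the list alone, 4 rose, and the median was -0.29 (camera adjusted p = 0.0207), with adjusted p = 0.350 with an estimated correlation. That call was lost with DESeq2 on the recovered reads (camera adjusted p = 0.0686), and with equal upper quartiles the split was 2 higher and 14 lower. The acyl-CoA synthetase gene Acsl3 was 1.66-fold lower and the elongase gene Elovl5 1.47-fold lower, while Acsl1 rose 2.23-fold and Gpam, which starts glycerolipid synthesis, 1.82-fold. Pnpla3 (0.65) and Acly (0.10), named after their values were seen, were the others that rose, and the largest fall, also named after its values were seen, was that of Mlxipl, a sugar-sensing transcription factor, at -3.30.

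Homologs of genes tied to Alzheimer's disease risk by genome-wide association moved in both directions. Ms4a6d, of the membrane-spanning 4A family, rose 7.61-fold from 1632 ± 134 to 12420.4 ± 919 normalized reads (SD, n = 8), Icam1, an adhesion molecule, 3.91-fold and the sheddase gene Adam17 1.65-fold. Sorl1, a sorting receptor for the amyloid precursor protein, was 2.10-fold lower, going from 43039.9 ± 1407 to 20469.6 ± 994. Of 47 genes 28 rose and 15 fell, with a median of 0.17, and the list was not called (camera adjusted p = 0.173). With equal upper quartiles the split was 23 higher and 18 lower.

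Energy metabolism genes moved in opposite directions. Slc16a3, a lactate exporter, rose 15.2-fold from 579 ± 82.9 to 8793 ± 536 normalized reads (SD, n = 8), the glycolytic activator gene Pfkfb3 2.44-fold, the hexokinase gene Hk2 1.82-fold and the lactate transporter gene Slc16a1 1.79-fold. Of 25 genes of glycolysis and hypoxia 20 rose, with a median of 0.39 (camera adjusted p = 3.2e-06), and adjusted p = 0.0652 with an estimated correlation. Pfkp (-0.42) and Pdk1 (-0.09), named after their values were seen, fell. All 21 of 21 oxidative phosphorylation genes fell, by 0.27 in the median (camera adjusted p = 1.07e-06), and adjusted p = 0.350 with an estimated correlation. Ndufs1 of complex I was 1.41-fold lower, Sdha of complex II 1.32-fold lower, and Atp5f1a and Ndufa4 1.34-fold and 1.37-fold lower.

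Genes of the unfolded protein response rose. Hspa5, the chaperone BiP of the endoplasmic reticulum, rose 1.65-fold from 73015 ± 1045 to 120178 ± 5128 normalized reads (SD, n = 8), with its partners Sdf2l1 and Hyou1 at 2.67-fold and 1.87-fold and the transcription factor gene Xbp1 at 1.59-fold. Of 20 genes of the unfolded protein response 18 rose, with a median of 0.55 (camera adjusted p = 3.2e-06), and adjusted p = 0.0652 with an estimated correlation; Dnajc3 (-0.08), named after its values were seen, fell. Antioxidant genes driven by NRF2 were divided, 13 higher and 10 lower of 23, at a median of 0.22 that did not pass (camera adjusted p = 0.152). The ferritin heavy chain gene Fth1 rose 3.83-fold to 1128250 ± 28022, the cystine transporter gene Slc7a11 12.8-fold, the glutathione reductase gene Gsr 2.85-fold and the haem oxygenase gene Hmox1 2.57-fold. Of 30 cytosolic ribosomal protein genes 27 rose by small amounts, at a median of 0.21 (camera adjusted p = 7.95e-06), and adjusted p = 0.463 with an estimated correlation. With equal upper quartiles 25 rose, at a median of 0.12. Rps2 (-0.12) and Rps4x (-0.06), named after their values were seen, fell. Heat shock and metallothionein genes were not called, with 3 higher and 9 lower of 14 and a median of -0.12 (camera adjusted p = 0.111). Hsp90ab1 (0.09), Mt2 (0.21) and Hspb1 (0.29), named after their values were seen, were those that rose.

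Matrix and growth factor genes changed unevenly. Mmp3, stromelysin 1, rose 222-fold from 1067 ± 173 to 236832 ± 28444 normalized reads (SD, n = 8), Thbs2, a thrombospondin, 3.23-fold and the membrane protease gene Mmp14 2.27-fold. Bcan, the brain proteoglycan brevican, was 2.98-fold lower. Of 29 matrix genes 18 rose and 7 fell, with a median of 0.34 (camera adjusted p = 0.0333), and adjusted p = 0.585 with an estimated correlation. Fgf2, basic fibroblast growth factor, rose 4.02-fold, while Igf1, insulin-like growth factor 1, was 5.34-fold lower, Fgf1 3.38-fold lower and the pleiotrophin gene Ptn 1.96-fold lower. Of 22 neurotrophic and growth factors 11 rose and 8 fell over all genes, or 11 and 9 adjusted over the list alone. Their median was 0.07, their mean -0.08 and the test's direction up without a call (camera adjusted p = 0.960). With replicates 7 and 8 alone the median turns to -0.02; with equal upper quartiles the split is 9 to 9 and the median turns to -0.02, and with equal totals 9 to 9 and -0.01.

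Several further lists were not called by camera. The lysosome list had 17 members higher and 7 lower of 29, at a median of 0.10 (camera adjusted p = 0.0634), and a split of 12 to 11 with equal upper quartiles. For targets of TGF-beta and YAP the numbers were 12 and 6 of 19, at 0.26 (camera adjusted p = 0.312), and for secreted and phagocytic regulators of synapses 6 and 11 of 20, at -0.15 (camera adjusted p = 0.377). Of 23 immediate early genes 9 rose over all genes and 8 adjusted over the list alone, 3 fell, and the median was 0.11 (camera adjusted p = 0.450), with a split of 5 to 4 and a median of 0.02 with equal upper quartiles. Those that fell, named after their values were seen, were Nr4a2 (-0.65), Dusp6 (-0.51) and Myc (-0.27). Mitochondrially encoded genes had 2 higher and 5 lower of 9, with a median of -0.13, a mean of 0.00146 and direction down (camera adjusted p = 0.501), and their share of all values was 1.58% ± 0.0833 without and 1.43% ± 0.103 with APOA1 (SD, n = 8). After the values were seen the members were named: mt-Nd1 (0.07) and mt-Co3 (0.99) rose, and mt-Nd4 (-0.24), mt-Nd5 (-0.20), mt-Nd6 (-0.16), mt-Nd2 (-0.13) and mt-Cytb (-0.12) fell.

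Transcripts typical of microglia were present in both groups. Cx3cr1, the fractalkine receptor of microglia, stood at 20998 ± 1389 normalized reads without APOA1 and 7739 ± 270.4 with it (SD, n = 8), 2.71-fold lower. Itgam, an integrin chain of myeloid cells, rose 4.65-fold from 2915 ± 227 to 13567 ± 1125, and Fcer1g, an Fc receptor chain, 4.11-fold. Oligodendrocyte lineage markers had 5 higher and 7 lower of 17, at a median of -0.09 (camera adjusted p = 0.312), and neuron markers 3 and 9 of 17, at -0.56 (camera adjusted p = 0.261). Named after their values were seen, Sox10, Bcas1, Mog, Mag and Pdgfra were the oligodendrocyte lineage markers that rose, the last by 1.11, and Stmn2 (0.69), Gad2 (2.43-fold) and Gad1 (1.58) the neuron markers. Endothelial markers had 4 higher over all genes, 3 adjusted over the list alone, and 4 lower of 13, at a median of -0.08 that turns to 0.10 with replicates 7 and 8 alone (camera adjusted p = 0.653); without these the split was 3 to 6. After the values were seen the members called with all libraries were named as Vwf, Eng, Cdh5 and Pecam1 (1.34) on the higher side and Erg (-2.73), Emcn (-2.64), Kdr (-1.50) and Flt1 (-0.77) on the lower. Of 13 pericyte and smooth muscle markers 5 rose and 6 fell, at a median of -0.39 that turns to 0.06 with replicates 7 and 8 alone (camera adjusted p = 0.441), the rising ones being Pdgfrb, Notch3, Vtn, Kcnj8 and Anpep, named after their values were seen. Fibroblast and meningeal markers had 6 higher and 6 lower of 17, 5 lower adjusted over the list alone, at a median of 0.01 that turns to -0.08 with equal upper quartiles and to -0.05 without replicates 7 and 8 (camera adjusted p = 0.805). Of 13 ependymal and choroid plexus markers 7 fell and 1, Rarres2 (0.85, named after its values were seen), rose, at -0.32 (camera adjusted p = 0.312).

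The libraries separated first by treatment and then by replicate number. The first principal component held 78.2% of the variance and parted the 8 APOA1 from the 8 untreated libraries. Replicates 7 and 8 of both groups stood apart from replicates 1 to 6 on the second component, which held 2.76%. Between these sets 2731 genes differed in limma's test, 1626 higher and 1105 lower in replicates 7 and 8. The sets were picked from that component of the same data, so the number is no independent evidence that they differ. The APOA1 response was tested for a difference between the sets by an interaction term, which limma called for 37 genes (955 at an unadjusted p under 0.05). Without replicates 7 and 8 the number of genes called was 11032, and with them alone 9189.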

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

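The Dixon test of each named gene, of the read total, of the share of the 10 most abundant genes and of the mitochondrially encoded share in each group was planned before the values were seen, and only the comparison with replicates 7 and 8 was added after the result. It compares the distance of the most extreme library from its neighbour with the range of the group, and chance would give about 1 group in 20. For genes the ratio was taken on log2(value + 1), while the levels given below are normalized reads. The test singled out 9 of 226 groups (3.98%), of which 2 concern replicates 7 or 8. Marco in untreated replicate 8 was highest at 37.5 against a median of 9.84 in the others (ratio 0.596), and Hspa5 in the same library was highest at 75252 against 72913 (ratio 0.556). Mmp3 in untreated replicate 4 was highest at 1451 against 1051 (ratio 0.596), and Hepacam in untreated replicate 5 lowest at 54307 against 56716 (ratio 0.693). Among the APOA1 libraries, Gpr34 in replicate 1 was lowest at 0 against 7.35 (ratio 0.631). In APOA1 replicate 4, Gbp2 was lowest at 31868 against 34335 (ratio 0.550) and Usp18 lowest at 4472 against 5163 (ratio 0.678). Gsr in APOA1 replicate 2 was highest at 13127 against 12213 (ratio 0.614), and Mki67 in APOA1 replicate 5 lowest at 1539 against 1777 (ratio 0.739). The cause was not tested for any of them, and none was left out.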

How the results depend on the processing

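The settings with replicates 7 and 8 left out, alone or as a covariate, and the minimum log2 change of 1, were chosen only after the result was seen; the others were planned. The minimum log2 changes and the adjusted p under 0.1 were set aside, which left 31 settings. Across these the 110 named genes kept direction and call in 3406 of 3406 combinations (Asb10, Cdc20b, Caln1 and Mcidas have no value at a mean of at least 50). Apart from Abca1 they were picked for large changes or small p, so this says little about other genes. The 16 called lists kept direction and call in 495 of 496 combinations when the estimated correlation is set aside. An adjusted p under 0.1 called 11879 genes, 5961 higher and 5918 lower. With an estimated correlation the lists called went from 16 to 0. The adjusted p then was 0.0652 for interferon-stimulated genes, antigen presentation, fatty acid oxidation, unfolded protein response and glycolysis, 0.0855 for NF-kB and A1 genes, and 0.108 for pan-reactive genes and proliferation. It was 0.350 for fatty acid synthesis and oxidative phosphorylation, 0.421 for homeostatic markers and A2 genes, 0.463 for complement and ribosomal proteins, and 0.585 for matrix. A minimum log2 change of 0.5 left 4127 genes, 1838 higher and 2289 lower, and one of 1 left 2005, 998 higher and 1007 lower. Leaving out 1 library at a time gave 11098 to 11235 genes, 5580 to 5652 higher and 5517 to 5595 lower, with 16 lists each time. On the recovered reads edgeR called 11299 genes and DESeq2 11310. Without replicates 7 and 8 there were 11032 genes, with them alone 9189, and with their set as a covariate 11554. Upper quartile scaling left 36.8% of calls on the higher side and equal totals 37.9%, against 50.4%. Replicate number as a block gave 11556, although equal numbers did not behave as paired, with correlations of -0.03 to 0.207 and 2 of 8 untreated libraries closest to their own number. For lists that were not called the direction of the test reversed with camera adjusted p close to 1: neurotrophic factors with the block (0.985), without replicates 7 and 8 (0.966), with the covariate (0.974), and without untreated replicate 1 (0.999) or APOA1 replicate 8 (0.987), in a range of 0.930 to 0.999 when 1 library was left out. The same held for fibroblast markers at a mean of at least 50 (0.992), and for the TGF-beta (0.949) and APOA1 binding (0.894) lists under DESeq2. DESeq2 lost fatty acid synthesis (0.0686) and gained NRF2 (0.00208) and pericyte markers (0.0349), and replicates 7 and 8 alone gained immediate early genes (0.00764). The cause was not tested.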

Other observations

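The families below were chosen only after the values were seen, and so were the tests of scaling, microglia, preparation, depth and handling further down; the tests of random splits, GC content and cell mix were fixed earlier. Of 17 families tested camera called 12 with the preset correlation. With an estimated correlation none was called, the lowest adjusted p from camera being 0.0557. Some families share genes with the lists above, such as Gbp2, Psmb8, Mmp3 and Mcm5. The family calls are therefore no independent support for those lists. Most members rose in several families of innate sensing and its effectors. Of 10 Toll-like receptor genes 7 rose, Tlr2 from 4663 ± 767 to 16662 ± 973 normalized reads (SD, n = 8) and Tlr1 5.91-fold, while Tlr9 fell 2.68-fold (median 0.77, camera adjusted p = 0.0362, and adjusted p = 0.387 with an estimated correlation). Guanylate-binding proteins, which attack vacuoles that hold pathogens, rose in 9 of 10 genes, Gbp6 63.9-fold (median 3.59, camera adjusted p = 3.79e-06, and adjusted p = 0.0557 with an estimated correlation). All 7 Schlafen genes rose, among them Slfn2 8.60-fold (median 2.79, camera adjusted p = 0.000189, and adjusted p = 0.0557 with an estimated correlation), and 8 of 9 MS4A genes did, Ms4a4a 22.3-fold (median 2.71, camera adjusted p = 0.000445, and adjusted p = 0.0655 with an estimated correlation). Members of these last 3 families are alike in sequence, so the division of reads among them is uncertain. Of 17 C-type lectins 9 rose and 6 fell, with Clec4e at 78.6-fold (median 1.71, camera adjusted p = 0.0362, and adjusted p = 0.169 with an estimated correlation), and of 12 PARP genes 9 rose, Parp14 6.86-fold (median 0.46, camera adjusted p = 0.00123, and adjusted p = 0.0655 with an estimated correlation). Matrix metalloproteinases rose in 13 of 18 genes, Mmp8 from 8.39 ± 2.41 to 1670.2 ± 149 and Mmp13 44.2-fold (median 1.01, camera adjusted p = 0.00240, and adjusted p = 0.0557 with an estimated correlation). Proteasome subunits rose in 38 of 49 genes by a median of 0.15 (camera adjusted p = 8.99e-05, and adjusted p = 0.211 with an estimated correlation), most for the immunoproteasome genes Psmb8 (3.00) and Psmb9 (2.01), and in 22 genes with equal upper quartiles.

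Other families fell. Of 69 potassium channel genes 40 fell and 16 rose, Kcnk2 from 5838 ± 431 to 1915 ± 154 normalized reads (SD, n = 8) and the astrocyte channel gene Kcnj10 1.55-fold lower (median -0.46, camera adjusted p = 0.00878, and adjusted p = 0.0557 with an estimated correlation). Histone genes fell in 43 of 55 cases (median -0.70, camera adjusted p = 0.000155, and adjusted p = 0.0557 with an estimated correlation), H2ax by 0.78 on the log2 scale, and the helicase genes of the Mcm family in 8 of 10, Mcm5 2.42-fold (median -0.80, camera adjusted p = 0.00108, and adjusted p = 0.0619 with an estimated correlation). Genes picked by symbols common among cilium and axoneme genes (Cfap, Dnah, Dnai, Rsph and Spag) fell in 42 of 80 cases (median -0.31, camera adjusted p = 0.00110, and adjusted p = 0.494 with an estimated correlation), and in 60 with equal upper quartiles. A shared symbol does not make every member a cilium gene, for example Spag5 (-1.06) and Spag9 (-0.39). Wnt ligands were lower in 9 of 16 without a list call (median -0.49, camera adjusted p = 0.117), Wnt7b 3.08-fold. Connexins were divided, with Gjb2 higher by 3.07 and Gja1 and Gjc3 lower at -1.11 and -1.07 (camera adjusted p = 0.965). Bone morphogenetic proteins (median -0.46, camera adjusted p = 0.947), voltage-gated sodium channels (-0.44, camera adjusted p = 0.636) and mitochondrial ribosome genes were not called either, the last at a median of 0.01 that turns to -0.08 with equal upper quartiles (camera adjusted p = 0.594).

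APOA1 libraries differed from untreated ones in a way that random grouping did not produce. Of 100 splits of the 16 libraries into 8 and 8, only 1, the real split, called as many genes as 11286, and the highest other split called 9063, with 7 APOA1 libraries on one side. Chance in how these libraries were grouped is therefore unlikely, at 1 of 100 splits, while 97 splits called no gene. Mixed splits keep the treatment difference in the spread within their sides, so few calls were likely in them. The splits cannot tell APOA1 apart from another difference shared by all libraries of a group, such as separate cultures, on which the labels are silent.

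NF-kB and interferon genes rose together with APOA1, and several causes could be asked for. Scaling of the deposited values was an unlikely cause, since the lowest median of both lists over 5 scalings was 2.95 on the log2 scale, and GC content or transcript length bias likewise, since at least 101% of each median was kept after the trend was removed. A larger share of microglia in the APOA1 libraries would raise all microglia markers if their levels per cell stayed the same, but 12 of them were lower. Levels per cell may have changed too, so a larger share together with such a change cannot be excluded. A microbial ligand carried in the protein preparation, such as endotoxin, may raise the same genes, and with 29 NF-kB members higher and no library given the preparation without the protein, the explanations cannot be told apart. Fewer microglia would lower all of their markers if levels per cell stayed the same, but 10 microglia markers were higher. Both expectations about microglia were written after the markers were seen to move in both directions, so their outcome was known. The counts speak only against a change in the number of microglia alone. A change of state in these cells may be part of the response, with or without a change in their number.

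Replicates 7 and 8 stood apart from replicates 1 to 6 in both groups, and immediate early genes were higher in them by a median of 0.61 on the log2 scale (0.612, camera adjusted p = 3.76e-45), 0.49 in untreated and 0.63 in APOA1 libraries, which may point to handling or harvest. Among the largest differences, chosen after their values were seen, were Ccrl2 (higher by 1.83) and Nr4a1 (higher by 1.54), and the NF-kB list was higher by 0.34 (camera adjusted p = 3.77e-14), 0.42 in untreated and 0.12 in APOA1 libraries. The sets were picked from these same data, so these p-values are no independent evidence that the sets differ. Both camera tests used only the preset correlation of 0.01. In the treatment comparison the estimated correlation was 0.775 for immediate early genes and 0.400 for the NF-kB list. Another mix of cell types may also take part, since ependymal markers differed by 0.221 and microglia markers by 0.18. Sequencing depth is an unlikely cause, as 3 of the libraries of replicates 7 and 8 had read totals inside the range of replicates 1 to 6 of their group. For GC content or transcript length the largest Spearman's rho was 0.177, and whether such a bias took part cannot be told apart from its absence; the fold changes of both sets had r = 0.953 across genes.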
